A study of Mus musculus with 18 samples.

How the data were processed

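RNA was measured by sequencing in 18 mouse hippocampus samples of 4 groups. The Control group (n = 3) is called blank control in the labels. The S-V group (n = 5) was rotated in a single direction with vision blocked, the D+V group (n = 5) was rotated in both directions with vision free, and the D-V group (n = 5) was rotated in both directions with vision blocked, the condition the labels call the Coriolis illusion. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected on oligo(dT) beads, libraries were made with an NEBNext Ultra kit, and fragments were size-selected and amplified by PCR. Sequencing was on an Illumina NovaSeq instrument. The series design text states that tissue was taken at once after the rotation.

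The deposited values were estimated counts per gene, many of them not whole numbers, with a column for each library, per the file headers and the values themselves. Per the submitters' processing notes, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2 were used, with no role or order given. The genome build, the annotation and the counting options are not given in the sources used here, so no coordinates are printed. Strand use in counting was not stated either, so reads of overlapping or antisense genes, and of near-identical copies such as the globin genes, could not be assigned with certainty. The table held 22063 Ensembl gene identifiers. Symbols were found for 21973 of them in a table of gene names, and the 90 without a symbol held 0.0562% of all counts. In every library 3732 genes were at 0. Library totals ran from 15.03 to 25.31 M estimated counts. PCR copies were not marked by molecular identifiers, so counts are not independent molecules.

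The estimated counts were rounded to whole numbers. Genes with enough counts by the filterByExpr rule of edgeR were kept, which left 14763 genes holding 99.97% of the counts. Scaling was by TMM. Differences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with all 18 libraries in a single fit of 4 group means, so that the 3 controls did not set the spread alone. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Common biological variation was 15.4%. The 7 comparisons were each rotated group against Control, the mean of the 3 rotated groups against Control, D-V against S-V, D-V against D+V, and D+V against S-V. The comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. The labels do not say that each sample is a separate animal, so p-values measure the spread between these samples.

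The 42 gene lists covered neuronal activity, stress responses, transmission, energy and translation, myelin, histones, cell types and neighbouring regions, and sex-linked genes. They were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the 42 lists in each comparison. Camera was repeated with a correlation estimated from the residuals, and fry tested whether the genes of a list moved in a shared direction without comparing them with other genes. For a list, the count of members called is given over all genes tested and adjusted over the list alone. A list score was the mean log2 CPM of its members (prior count 2) minus the mean over all libraries. An exact permutation test of list scores was added after seeing the data.

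Genes were named by a fixed rule among genes with a mean log2 CPM of at least 1 and a regular symbol: the 6 rises and 6 falls with the smallest p among called genes, and the 4 rises and 4 falls with the largest fold change among called genes. Where fewer than 12 genes passed, the 3 smallest unadjusted p in each direction were given as values only. The 4 members with the smallest p were taken from each list described. Fos, Arc, Egr1, Npas4, Fkbp5, Sgk1, Tsc22d3, Bdnf, Hrh1 and Hrh3 were to be named in any case. Results for some genes that the rule selects are not reported here.

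The tests were run on simulated data, with each gene drawn independently. With counts drawn for 14763 genes at the depths of D+V and Control, edgeR recovered 32.7% of 150 genes changed by 1.3-fold, 53.3% of those changed by 1.5-fold, 86% of those changed by 2-fold and 96.7% of those changed by 4-fold, and 5.84% of its calls were false. In the same data 13.4% of the calls of DESeq2 1.42.0 and 6.37% of those of limma voom were false. A list of microglia markers raised 1.3-fold in simulated D+V libraries was called at an adjusted p of 5.82e-41, with 0 of the other lists called. As simulated genes were independent, this could not show false list calls that come from correlation between genes. Other divisions of the real D+V and Control libraries called a median of 14 lists.

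Alternatives fixed in advance were other scaling factors, a stricter and an open filter, DESeq2, limma voom with quality weights, only the groups compared, the replicate number as a block, the first surrogate variable (sva 3.50.0), a log2 fold change minimum of 1, and each library left out in turn. Alternatives chosen after seeing the data were a choroid plexus marker score as a covariate, removal of the trend of each library on transcript GC content and length, leaving out 6 libraries rich in choroid plexus markers, and leaving out D+V libraries 2, 3 and 5. The 6 libraries were S-V replicates 2 and 4, D+V replicates 2 and 5, and D-V replicates 3 and 4. No Control library was among them, so fits without them lose rotated libraries only. GC content and length came from GENCODE mouse transcripts M21, matched on Ensembl identifiers for 99.86% of the genes used. No library pair was a repeat deposit: over 33 pairs within groups the chi-square per degree of freedom ran from 5.73 to 59.5. Figures were drawn with matplotlib 3.10.9.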

Results

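The series asked how rotation that disturbs the sense of orientation alters transcripts of the mouse hippocampus, the brain region of spatial memory. Totals per library were 20.44 to 22.17 M estimated counts in Control (n = 3), 15.56 to 24.28 M in S-V (n = 5), 15.03 to 25.31 M in D+V (n = 5) and 15.39 to 21.43 M in D-V (n = 5). Between 15938 and 16493 genes had a count in each library. Mitochondrially encoded transcripts made up 8.08% ± 0.749 of counts in Control (SD, n = 3), 8.79% ± 0.423 in S-V, 8.33% ± 0.451 in D+V and 8.46% ± 0.89 in D-V (SD, n = 5 each).

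The comparison of S-V with Control asked what rotation in a single direction without vision changed. No single gene passed the test. Glucocorticoid-responsive genes, which the stress hormone receptor induces, were higher in S-V by a mean log2 of 0.22. Of the 36 measured members 28 were positive, and the list score of 4 of 5 S-V libraries lay above all 3 controls. Its leading members were Sesn1 (log2 0.24, SE 0.08), a stress-induced regulator of growth signalling, Errfi1 (0.32, SE 0.11), a feedback inhibitor of the EGF receptor, Tsc22d3 (0.30, SE 0.11), which encodes the leucine zipper protein GILZ, and Plekhf1 (0.53, SE 0.22), an endosomal protein. The list rose at an adjusted p of 0.000823 with the preset correlation, with adjusted p = 0.656 with an estimated correlation. Its mean was 0.33 without Control replicate 2, 0.11 without S-V replicate 4 and 0.085 with the 6 libraries rich in choroid plexus markers left out.

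Heat shock and chaperone genes, which help proteins fold, rose in S-V by a mean log2 of 0.12 (adjusted p 0.000823 at the preset correlation, adjusted p = 0.883 with an estimated correlation). Over all genes tested 0 of 26 members were called, and adjusted over the list alone 3 rose: Dnaja1 (0.32, SE 0.08), an HSP40 partner of HSP70, Hspd1 (0.23, SE 0.06), the mitochondrial chaperonin, and Cacybp (0.29, SE 0.09), a calcyclin-binding protein. Hspa4 was at 0.18 (SE 0.07). Markers of thalamus and habenula, regions next to the hippocampus, fell in S-V by a mean log2 of −0.44, with 21 of 24 members negative (adjusted p 0.00215 at the preset correlation, adjusted p = 0.656 with an estimated correlation). Synpo2, an actin-binding protein, was at −0.47 (SE 0.17), Irx1 at −1.12 (SE 0.50), Prkcd at −0.69 (SE 0.34) and Amotl1 at −0.31 (SE 0.17). Members of these lists adjusted over the list alone numbered 0 for glucocorticoid response and 0 for thalamus and habenula.

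In all 12 of the 42 lists were called at the preset correlation in S-V against Control, 6 higher and 6 lower, and 0 with an estimated correlation (smallest adjusted p 0.656) or with fry (smallest 0.169). Only the 3 lists just described kept the call in each fit with a library left out. The other 9 lost it in at least 1 such fit. Among them, the cytosolic ribosomal protein genes were at 0.12 (adjusted p = 0.883 with an estimated correlation), at 0.05 and no longer called without Control replicate 3, at 0.04 and still called with the trends on GC content and length removed, and at 0.19 with the 6 libraries rich in choroid plexus markers left out, and endothelial and pericyte markers were at −0.14 (adjusted p = 0.883 with an estimated correlation) and at −0.04 without Control replicate 2. Choroid plexus markers were at 1.33 (adjusted p = 0.908 with an estimated correlation), at 1.01, 0.92 and 0.97 and no longer called without Control replicate 3, S-V replicate 2 or S-V replicate 4, and at −0.21 when the 6 libraries rich in those markers were left out. The choice of libraries by these same markers favours the last value. Striatum markers were at −0.30 (adjusted p = 0.883 with an estimated correlation) and at 0.15 without Control replicate 1.

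At the gene level edgeR called 0 of 14763 genes in S-V against Control. The smallest adjusted p was 0.0904, 1973 genes had an unadjusted p under 0.05 where chance gives 738 (1240 with the trends on GC content and length removed), DESeq2 called 212 and limma voom 318. As values, the 3 falls with the smallest p were Pdgfrb, the pericyte receptor for PDGF-B (log2 −0.49, SE 0.08), Dbn1, which encodes the dendritic spine protein drebrin (−0.32, SE 0.06), and Sptbn4, a spectrin of the axon initial segment (−0.33, SE 0.06). The 3 on the other side were Pdcl, a phosducin-like protein (0.46, SE 0.09), Otud6b, a deubiquitinase (0.31, SE 0.06), and Cbx1, the heterochromatin protein HP1 beta (0.40, SE 0.08). All 5 S-V libraries lay beyond all 3 controls for each of the 6, which the choice of genes by small p favours. Without Control replicate 1 the count was 1, and with the trends on GC content and length removed it was 5.

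The comparison of D+V with Control asked what rotation in both directions with vision changed, and it was the single comparison in which edgeR called genes: 114 rose and 25 fell. Changes were small, with a median absolute log2 fold change of 0.386 and a single gene past 1, the weakly expressed Mpp4 (−1.82), named here after its values were seen. The largest named rise was in Elavl2 (ENSMUSG00000008489), a neuronal RNA-binding protein of the Hu family, from 47.7 ± 2.79 CPM in Control (SD, n = 3) to 79 ± 12.2 in D+V (SD, n = 5), log2 0.73 (SE 0.10, adjusted p 0.00974). The strongest falls by p were in Pdgfrb (ENSMUSG00000024620), from 31.3 ± 1.26 to 22 ± 1.98 CPM, log2 −0.51 (SE 0.08, adjusted p 0.0153), and in Dbn1 (ENSMUSG00000034675), from 330 ± 11.3 to 259 ± 15.3 CPM, log2 −0.35 (SE 0.06, adjusted p 0.0157).

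Among the other named genes Tmx3, a disulfide isomerase of the endoplasmic reticulum, rose by a log2 of 0.43 (SE 0.07), Hspa13, a microsomal HSP70 relative, by 0.43 (SE 0.07), and Ipo7, a nuclear import receptor, by 0.42 (SE 0.07). The transcription factors Sp3 (0.49, SE 0.08), Zbtb33, also called Kaiso (0.51, SE 0.09), St18 (0.59, SE 0.13) and the zinc finger gene Zfp748 (0.59, SE 0.13) rose too. Ube3a, the ubiquitin ligase gene lost in Angelman syndrome, rose by 0.60 (SE 0.14), though an antisense transcript crosses this gene in neurons and strand use in counting was not stated. Named falls were in Cldn5, a tight junction protein of brain endothelium (−0.58, SE 0.13), Clasrp, a splicing factor relative (−0.49, SE 0.09), Zfp575 (−0.53, SE 0.12), Ppp1r10, a nuclear partner of protein phosphatase 1 (−0.34, SE 0.07), Sh2d5 (−0.31, SE 0.07) and Por, the electron donor of cytochrome P450 enzymes (−0.28, SE 0.06). Adjusted p of the 17 named genes ran from 0.00974 to 0.0472. All 5 D+V libraries lay beyond all 3 controls for each, except Cldn5 and Ube3a, for which 4 of 5 did. The choice of genes by these same values favours this. Of all tested genes 7.63% had no overlap between D+V and Control libraries.

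**Figure D1:**
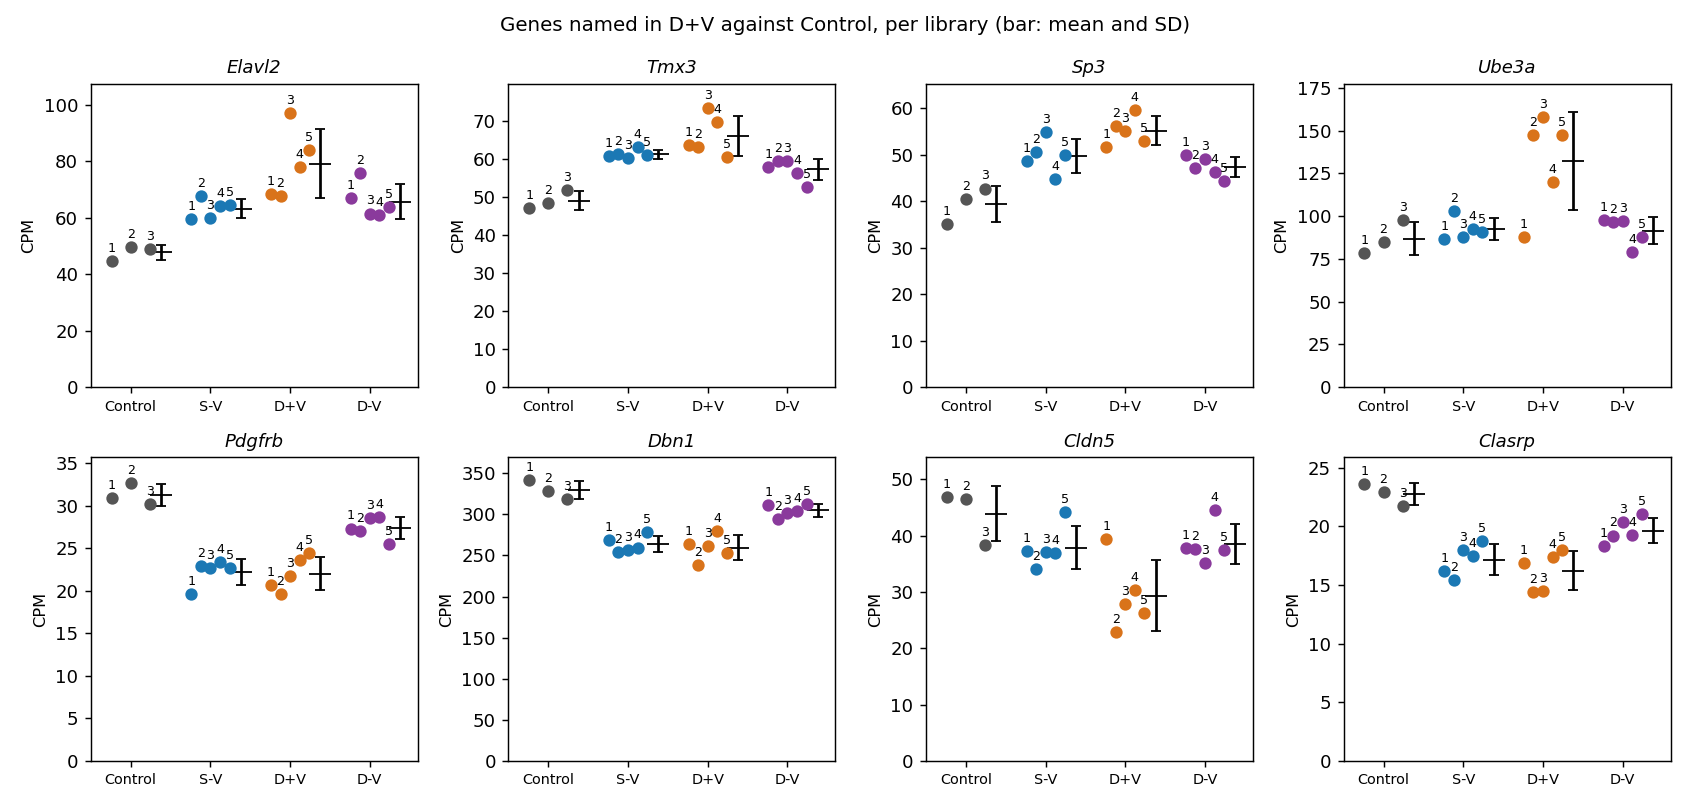
CPM (vertical axes, from 0) of 8 genes named in D+V against Control, in each library of the 4 groups; numbers are replicates and bars are the group mean and SD. D+V libraries lie above all controls for Elavl2, Tmx3 and Sp3 and below them for Pdgfrb, Dbn1 and Clasrp, while Ube3a in D+V replicate 1 and Cldn5 in D+V replicate 1 lie within the range of the controls.

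The 139 calls in D+V against Control depended on single libraries. The count was 0 without Control replicate 1, 2 without Control replicate 2, 400 without Control replicate 3, 1260 without D+V replicate 1, 13 without D+V replicate 3, 30 without D+V replicate 4 and 26 without D+V replicate 5. It was also 0 when only D+V and Control entered the fit, 4 with a replicate block, 759 by DESeq2 and 1882 by limma voom, with 2601 genes at an unadjusted p under 0.05 in edgeR (1237 with the trends on GC content and length removed). None of the 139 was called in D-V against D+V (116 at an unadjusted p under 0.05) or in D+V against S-V (72), so the calls were not shown to be particular to D+V. All 139 had the same direction in S-V against Control and 138 in D-V against Control, which the shared controls and the choice of genes by these same controls favour.

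The called genes differed from others in base composition. The genes that rose had a median transcript GC content of 40.5% and a median length of 5054 bases, those that fell 58.2% and 2982, and all tested genes 50.3% and 3205. Random genes matched on expression had a median GC content between 48.7% and 51.7%. Across 12817 genes, which are not independent replicates, the log2 fold change in D+V against Control had a Spearman correlation of −0.608 with GC content and 0.389 with length. In S-V and D-V against Control the correlation with GC content was −0.497 and −0.3. With each library's trends on GC content and length removed, 0 of the 139 genes were called (smallest adjusted p 0.0641), their median absolute log2 fold change was 0.184 in place of 0.386, and 138 kept their direction.

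**Figure D2:**
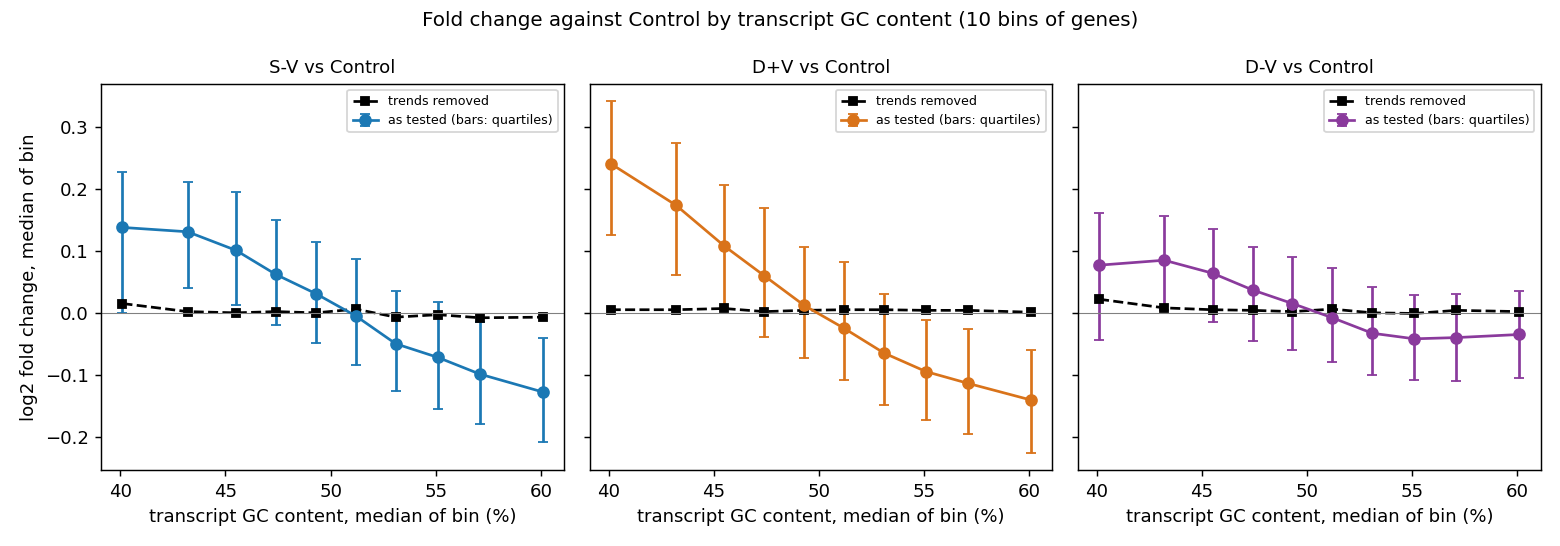
Median log2 fold change against Control (vertical axis) of genes in 10 bins of transcript GC content (horizontal axis, percent), for S-V, D+V and D-V; bars are the quartiles of the genes in a bin and dashed lines the values with the trends removed. In D+V the median goes from 0.24 in the bin at 40.1% GC to −0.14 in the bin at 60.1%, in S-V from 0.14 to −0.13 and in D-V from 0.08 to −0.04.

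By gene group, endothelial and pericyte markers fell in D+V by a mean log2 of −0.25, with 20 of 24 members negative and the scores of 4 of 5 libraries below all controls. Over all genes 2 members fell, Pdgfrb and Cldn5, and adjusted over the list alone 3 did, with Esam, an endothelial adhesion molecule (−0.48, SE 0.14). Pecam1, another endothelial adhesion molecule, was at −0.33 (SE 0.12). The list had an adjusted p of 2.35e-05 at the preset correlation, with adjusted p = 0.688 with an estimated correlation, and its mean was −0.15 without Control replicate 2, −0.17 with the 6 libraries rich in choroid plexus markers left out and −0.14, no longer called, without D+V libraries 2, 3 and 5. Immediate early genes, which neuronal firing induces, fell by a mean log2 of −0.26 with 29 of 34 members negative, although 0 members were called over all genes and 0 adjusted over the list alone. Egr2 was at −0.99 (SE 0.30), Npas4 at −0.67 (SE 0.22), Atf3 at −0.95 (SE 0.33) and Klf2 at −0.53 (SE 0.19). This list too had an adjusted p of 2.35e-05 at the preset correlation and adjusted p = 0.688 with an estimated correlation, and its mean was −0.17 with the trends on GC content and length removed (adjusted p 0.00208 at the preset correlation).

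The remaining 5 of the 7 lists called in D+V against Control each lost the call in at least 1 fit with a library left out. GABA signalling genes were at a mean log2 of 0.15 (adjusted p = 0.894 with an estimated correlation). The list was no longer called without Control replicate 2 (0.13), D+V replicate 3 (0.12), D+V replicate 4 (0.16) or D+V replicate 5 (0.14), nor with the trends on GC content and length removed (0.05, adjusted p 0.503) or without D+V libraries 2, 3 and 5 together (0.065). Astrocyte markers were at 0.13 (adjusted p = 0.938 with an estimated correlation), and Aqp4, the astrocyte water channel, rose by 0.43 (SE 0.10, adjusted p 0.0411), 1 of 2 members that rose adjusted over the list alone. Their list was no longer called without Control replicate 2 (0.10), Control replicate 3 (0.13), D+V replicate 2 (0.10), D+V replicate 3 (0.12) or D+V replicate 5 (0.10), nor with the 6 libraries rich in choroid plexus markers left out (0.07), with the choroid plexus score as a covariate (0.12) or with the first surrogate variable (0.12), and its mean was −0.002 without D+V libraries 2, 3 and 5 together. Red blood cell markers were at 1.06 (adjusted p = 0.688 with an estimated correlation), at 0.57 without D+V replicate 2 and no longer called without Control replicate 3 (0.95), with the 6 libraries rich in choroid plexus markers left out (0.51) or without D+V libraries 2, 3 and 5 (0.29). Thalamus and habenula markers were at −0.43 and striatum markers at −0.29, each with adjusted p = 0.688 with an estimated correlation. The thalamus and habenula list was no longer called without Control replicate 2 (−0.32) or D+V replicate 4 (−0.30), nor the striatum list without Control replicate 1 (0.16). A replicate block also ended the calls of the thalamus and habenula (−0.33), GABA signalling (0.15) and astrocyte (0.13) lists. With fry 0 lists passed (smallest adjusted p 0.123). Nectin3, an adhesion molecule in the list of CA3 pyramidal cell markers, also rose (0.47, SE 0.10, adjusted p 0.0411), as did Elavl2 of the same list.

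The comparison of D-V with Control asked what the Coriolis condition, rotation in both directions without vision, changed. Thalamus and habenula markers were lower in D-V, by a mean log2 of −0.82, with 23 of 24 members negative and all 5 D-V libraries below all 3 controls. The mean score was 0.42 ± 0.24 in Control (SD, n = 3) and −0.28 ± 0.16 in D-V (SD, n = 5), with 0.03 ± 0.16 in S-V and −0.01 ± 0.31 in D+V (SD, n = 5). Over all genes 0 members were called, and adjusted over the list alone 8 fell. Synpo2 went from 11.7 ± 2.71 CPM in Control to 6.81 ± 0.637 in D-V (log2 −0.78, SE 0.17), Tcf7l2, a Wnt pathway transcription factor of thalamic neurons, from 9.27 ± 2.99 to 4.16 ± 1.1 CPM (−1.15, SE 0.27), and Ramp3, a receptor activity-modifying protein, from 8.34 ± 4.32 to 3.98 ± 0.565 CPM (−1.07, SE 0.28). Gbx2, a homeobox gene of the thalamus, was near the limit of detection, at 0.811 ± 0.462 CPM in Control and 0.0404 ± 0.0413 in D-V.

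Of the lists in D-V against Control this was the only one that passed all 3 list tests, with the preset correlation (adjusted p 1.21e-14), with an estimated correlation (adjusted p 0.00957) and with fry (adjusted p 0.0161). It rested on few controls. With an estimated correlation the adjusted p was 0.059 without Control replicate 2 and between 0.0107 and 0.0451 without any other library of the 2 groups, and with fry it was 0.0799 without Control replicate 1, 0.106 without Control replicate 2, 0.101 without D-V replicate 2 and 0.0522 without D-V replicate 4. An exact two-sided permutation test of the list score gave p = 0.0179, the smallest that 56 splits allow, and 0.375 after adjustment over the 42 lists. With the trends on GC content and length removed the adjusted p with an estimated correlation was 0.0203.

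**Figure D3:**
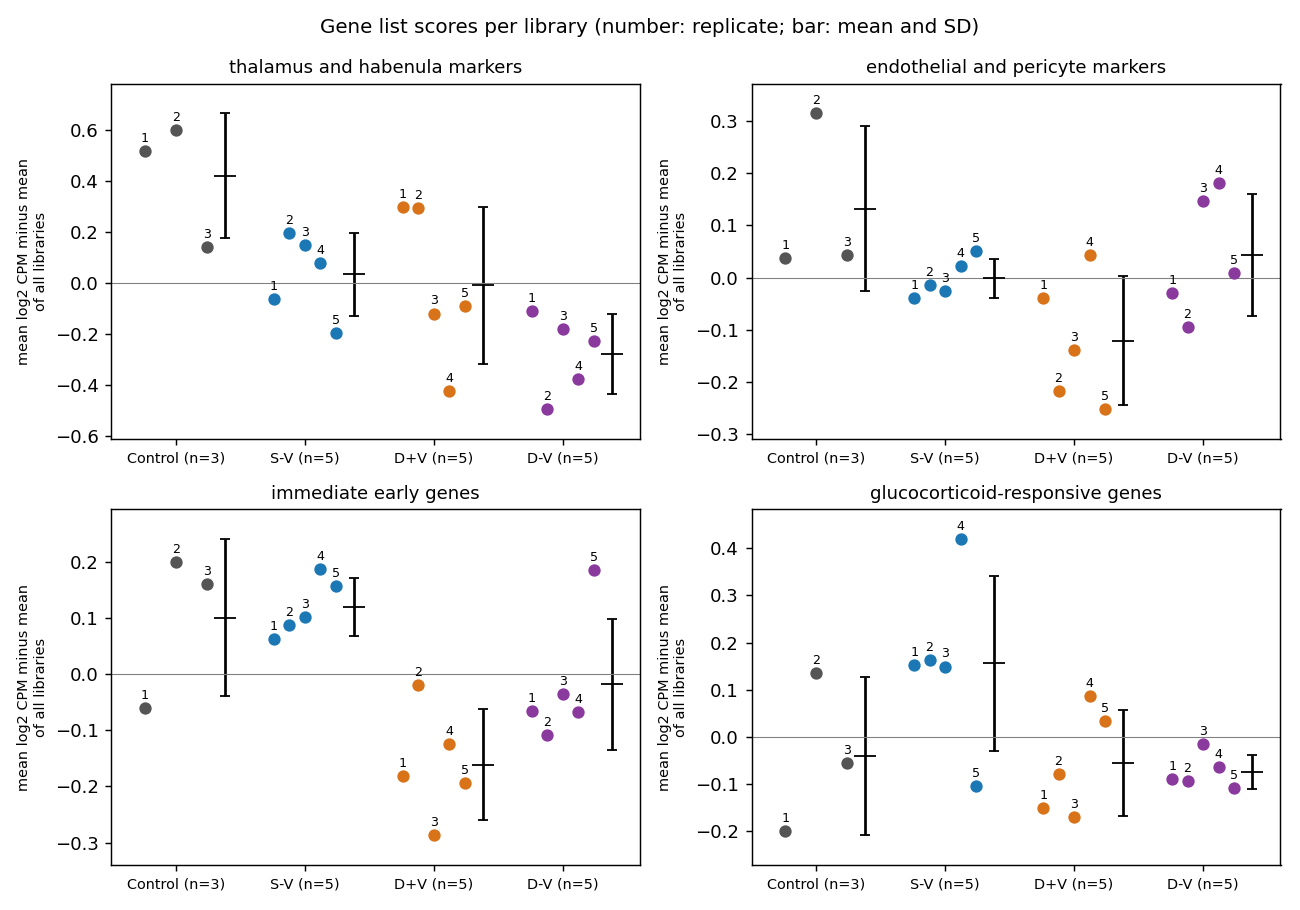
Scores of 4 gene lists in each library, as the mean log2 CPM of the members minus the mean over all libraries (vertical axes); numbers are replicates and bars are the group mean and SD (n in the axis labels). The 5 D-V libraries lie below the 3 controls for thalamus and habenula markers, and the 5 D+V libraries lie below the 5 S-V libraries for immediate early genes.

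The labels name the tissue as hippocampus, and the thalamus and habenula list was fixed as a marker of neighbouring tissue. More of that tissue in the dissected control samples would give the same difference. This was not tested, so it cannot be told apart here from a response to rotation. Other groups shifted in D-V against Control as well. Red blood cell markers rose by a mean log2 of 0.86, with 11 of 12 members positive and all 5 D-V libraries above all controls (adjusted p 8.37e-07 at the preset correlation, adjusted p = 0.305 with an estimated correlation). The globin genes led this list, with Hbb-bs at 1.19 (SE 0.46), Hba-a1 at 1.18 (SE 0.47), Hbb-bt at 1.20 (SE 0.49) and Hba-a2 at 1.15 (SE 0.48), and reads may be split among these near-identical copies. Genes of the endoplasmic reticulum stress response rose by a mean log2 of 0.16, with 25 of 28 positive (adjusted p 6.25e-05 at the preset correlation, adjusted p = 0.385 with an estimated correlation). Their leading members were Dnajc3 (0.34, SE 0.12) and Dnajb9 (0.22, SE 0.08), co-chaperones of the endoplasmic reticulum, Hspa5 (0.49, SE 0.20), the chaperone BiP, and Herpud1 (0.17, SE 0.08), a degradation factor. Adjusted over the list alone 0 members of either list passed.

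The other 8 of the 11 lists called in D-V against Control lost the call in at least 1 fit with a library left out. Cholinergic signalling genes were at a mean log2 of −0.53 (adjusted p = 0.282 with an estimated correlation), and adjusted over the list alone 2 members fell, Chrna3 (−1.27, SE 0.31) and Chrnb3 (−1.68, SE 0.49), nicotinic receptor subunits with high levels in habenula. That list was no longer called without Control replicate 3 (−0.46) or with the 6 libraries rich in choroid plexus markers left out (−0.37). Choroid plexus markers were at 1.92 (adjusted p = 0.956 with an estimated correlation), at 1.61, 0.88 and 1.75 and no longer called without Control replicate 3, D-V replicate 3 or D-V replicate 4, and at −1.15 when the 6 libraries rich in them were left out. Leaving out libraries by these same markers favours that last value. Dentate granule cell markers were at −0.17 (adjusted p = 0.956 with an estimated correlation) and at −0.35 without Control replicate 1. Their list was no longer called without Control replicate 2 (−0.13), Control replicate 3 (−0.01), D-V replicate 2 (−0.14), D-V replicate 3 (−0.16) or D-V replicate 4 (−0.17). It was not called either with a replicate block (−0.16), the first surrogate variable (−0.15) or the choroid plexus score as a covariate (−0.155). Nor was it called with the 6 libraries rich in choroid plexus markers left out (−0.14).

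At the gene level edgeR called 0 genes in D-V against Control (smallest adjusted p 0.479). At an unadjusted p under 0.05 there were 888, close to the 738 chance gives, and DESeq2 called 3 and limma voom 0. As values, the falls with the smallest p were Zfp994, a zinc finger gene (log2 −1.03, SE 0.20), Olfr1385, an olfactory receptor gene (−0.50, SE 0.10), and Synpo2. On the other side were Cfap300, a gene of motile cilia (0.73, SE 0.16), Elavl2 (0.46, SE 0.10) and Cbx1 (0.33, SE 0.08). Zfp994 and Olfr1385 belong to large families of similar genes, so their counts are uncertain.

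The mean of the 3 rotated groups against Control asked what the rotations shared. Thalamus and habenula markers fell by a mean log2 of −0.56, with 22 of 24 members negative and 11 of 15 rotated libraries below all controls (adjusted p 9.08e-07 at the preset correlation, adjusted p = 0.18 with an estimated correlation, fry 0.0581). Over all genes 0 members fell, and adjusted over the list alone 4 did: Synpo2 (−0.63, SE 0.14), Tcf7l2 (−0.84, SE 0.22), Ramp3 (−0.76, SE 0.23) and Shox2, a homeobox gene of the habenula (−2.03, SE 0.68). This list alone of the 7 called kept the call in every fit with a library left out, and 0 lists were called with an estimated correlation or fry.

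Of single genes edgeR called 0 in the mean of the rotated groups, with 1902 at an unadjusted p under 0.05 (1142 with the trends on GC content and length removed), a smallest adjusted p of 0.0752, and 259 called by DESeq2 and 381 by limma voom. The count was 3 without Control replicate 1, 6 without D+V replicate 1, 1 without D+V replicate 2 and 1 without D+V replicate 3. As values, Elavl2 was at 0.53 (SE 0.09), Otud6b at 0.30 (SE 0.05) and Tmx3 at 0.32 (SE 0.06), and Pdgfrb at −0.40 (SE 0.07), Dbn1 at −0.26 (SE 0.05) and Leng8 at −0.40 (SE 0.08). For each of these 6 all 15 rotated libraries lay beyond all 3 controls, which the choice of genes by small p favours.

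The same 3 control libraries entered each comparison, so fold changes against them share chance values. Fold changes of S-V and D+V correlated at 0.658 across genes, against 0.645 in 20 simulations of unchanged groups, those of S-V and D-V at 0.691 against 0.635, and those of D+V and D-V at 0.664 against 0.632. The SD of the simulated correlations was 0.03, 0.037 and 0.024 in the same order. The covariance exceeded the simulated one by 0.0136, 0.0167 and 0.0177. The 3 controls were too few to split, so part or all of the excess may come from them. The simulations drew each gene independently and held no trend on GC content or length. They cannot show how far such trends add to the correlations, and their SD leaves this out.

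The comparison of D-V with S-V asked what a second direction of rotation added when vision was blocked. Glucocorticoid-responsive genes were lower in D-V by a mean log2 of −0.28, with 34 of 36 members negative. Over all genes 0 members fell, and adjusted over the list alone 11 did. Plekhf1 went from 7.01 ± 1.55 CPM in S-V to 4.1 ± 0.612 in D-V (SD, n = 5 each; log2 −0.78, SE 0.19), Sgk1, a kinase induced by corticosteroids, from 108 ± 22.6 to 73.3 ± 10.8 CPM (−0.56, SE 0.16), Tsc22d3 differed by −0.36 (SE 0.10) and Sesn1 by −0.24 (SE 0.07). The adjusted p was 5.31e-12 at the preset correlation, with adjusted p = 0.109 with an estimated correlation, and the mean was −0.18 without S-V replicate 4 and −0.16 with the 6 libraries rich in choroid plexus markers, S-V replicate 4 among them, left out.

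Cytosolic ribosomal protein genes fell in D-V against S-V by a mean log2 of −0.16, with 79 of 79 members negative, led by Rps15a (−0.20, SE 0.05), Rpl34 (−0.31, SE 0.10), Rpl10 (−0.25, SE 0.08) and Rpl39 (−0.39, SE 0.13), but 0 passed over all genes or adjusted over the list alone. The adjusted p was 5.25e-24 at the preset correlation and adjusted p = 0.561 with an estimated correlation. The mean was −0.09 with the trends on GC content and length removed and −0.315 with the 6 libraries rich in choroid plexus markers left out. Microglia markers fell by −0.13 with 20 of 21 negative (adjusted p 3.93e-06 at the preset correlation, adjusted p = 0.561 with an estimated correlation). Ctss, a lysosomal protease, fell adjusted over the list alone (−0.26, SE 0.07), with 0 members called over all genes. Dentate granule cell markers were at −0.21 (adjusted p = 0.564 with an estimated correlation), immediate early genes at −0.14 (adjusted p = 0.561 with an estimated correlation) red blood cell markers at 0.56 and thalamus and habenula markers at −0.38 (each with adjusted p = 0.561 with an estimated correlation). With the 6 libraries rich in choroid plexus markers left out the lists of immediate early genes (−0.085) and thalamus and habenula markers (−0.28) were no longer called. Genes of AMPA, NMDA and kainate receptors rose by 0.09 (adjusted p 0.000843 at the preset correlation, adjusted p = 0.564 with an estimated correlation), led by Grin2d (0.39, SE 0.10), the member called adjusted over the list alone, and were at 0.16 with those 6 libraries left out.

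In all 16 lists were called in D-V against S-V, 6 higher and 10 lower, and 8 of them kept the call in every fit with a library left out. With an estimated correlation or fry 0 were called. By edgeR 0 genes were called (smallest adjusted p 0.61), with 929 at an unadjusted p under 0.05, 11 by DESeq2 and 0 by limma voom. As values, Cspg4, the NG2 proteoglycan of oligodendrocyte precursors and pericytes, was at 0.48 (SE 0.10), Sptbn4 at 0.25 (SE 0.06) and Col4a2, a basement membrane collagen, at 0.35 (SE 0.08). Mat2a, which makes S-adenosylmethionine, was at −0.22 (SE 0.05), Cd38, an NAD glycohydrolase, at −0.42 (SE 0.10), and Plekhf1 at −0.78. For each of the 6 the 5 D-V libraries did not overlap the 5 S-V libraries, which the choice of genes by small p favours.

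The comparison of D-V with D+V asked what loss of vision added to rotation in both directions. Endothelial and pericyte markers were higher in D-V by a mean log2 of 0.16, with 21 of 24 positive (adjusted p 0.000279 at the preset correlation, adjusted p = 0.593 with an estimated correlation). Adjusted over the list alone 2 rose, Pdgfrb (0.32, SE 0.07) and Cldn5 (0.39, SE 0.11), with 0 over all genes. Astrocyte markers were lower by −0.13 with 16 of 20 negative (adjusted p 0.000404 at the preset correlation, adjusted p = 0.593 with an estimated correlation), and adjusted over the list alone 7 fell, led by Aqp4 (−0.35, SE 0.08), Slc4a4, a bicarbonate transporter (−0.28, SE 0.08), Gja1, the gap junction protein connexin 43 (−0.22, SE 0.07), and Acsbg1 (−0.26, SE 0.09), again with 0 over all genes. Genes of endoplasmic reticulum stress were higher by 0.14 (adjusted p 0.000655 at the preset correlation, adjusted p = 0.593 with an estimated correlation), with Atf4, a stress-response transcription factor, at 0.18 (SE 0.06) and the chaperone Calr at 0.26 (SE 0.10). These 3 lists kept the call with each library left out and lost it when D+V libraries 2, 3 and 5 were left out (means 0.045, 0.001 and 0.056 in the order given) and when the 6 libraries rich in choroid plexus markers were (−0.007, −0.05 and 0.07).

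In D-V against D+V 7 lists were called, and 0 with an estimated correlation or fry. By edgeR 0 genes were called (smallest adjusted p 0.0705), with 2003 at an unadjusted p under 0.05 (1234 with the trends on GC content and length removed), 277 by DESeq2 and 819 by limma voom. The count was 1230 without D+V replicate 1 and 62 without D+V replicate 4. As values, Snrnp70, a core protein of the U1 splicing particle, was at 0.35 (SE 0.06), Dbn1 at 0.23 (SE 0.05) and Phf1, a Polycomb partner, at 0.30 (SE 0.07). Sept7, a septin of the cytoskeleton, was at −0.33 (SE 0.06), Zfp994 at −0.93 (SE 0.18) and Fut9, which makes the Lewis X glycan, at −0.86 (SE 0.16).

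The comparison of D+V with S-V changed the direction of rotation and vision together, so neither can be separated in it. Immediate early genes were lower in D+V by a mean log2 of −0.28, with 32 of 34 negative and all 5 D+V libraries below all 5 S-V libraries. Over all genes 0 fell, and adjusted over the list alone 6 did, led by Klf2 (−0.73, SE 0.17), Dusp5, a phosphatase of ERK (−0.49, SE 0.13), Egr2 (−0.96, SE 0.27) and Junb (−0.35, SE 0.11). The adjusted p was 5.48e-10 at the preset correlation, with adjusted p = 0.191 with an estimated correlation, and 0.0449 with fry. An exact two-sided permutation test of the score gave p = 0.00794, the smallest that 252 splits allow, and 0.333 after adjustment over 42 lists. Glucocorticoid-responsive genes were at −0.24 (adjusted p 2.12e-07 at the preset correlation, adjusted p = 0.28 with an estimated correlation), with Plekhf1 at −0.85 (SE 0.19). Their mean was −0.13 without S-V replicate 4 and −0.11 with the 6 libraries rich in choroid plexus markers left out.

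A further 4 lists were higher in D+V than in S-V at the preset correlation only. The mean log2 was 0.13 for AMPA, NMDA and kainate receptor genes, with Gria2 at 0.39 (SE 0.10), 0.15 for GABA signalling genes, with Gabrb1 at 0.64 (SE 0.16), 0.12 for postsynaptic density and plasticity kinase genes, with Camk4 at 0.62 (SE 0.14), and 0.14 for voltage-gated channel genes, with Cacnb4 at 0.46 (SE 0.12). Adjusted p at the preset correlation ran from 3.96e-05 to 0.000857, and with an estimated correlation adjusted p was 0.646, 0.608, 0.646 and 0.646. Adjusted over the list alone 3, 1, 5 and 5 members rose, with 0 over all genes. All 4 lists lost the call once the trends on GC content and length were removed, with means of 0.03, 0.085, 0.04 and 0.01. Without D+V libraries 2, 3 and 5 the means of the last 3 were 0.07, 0.04 and 0.08, and the postsynaptic density list was no longer called with the 6 libraries rich in choroid plexus markers left out (0.08). In all 15 lists were called, 1 of them with fry and 0 with an estimated correlation. By edgeR 0 genes were called (smallest adjusted p 0.189), with 1892 at an unadjusted p under 0.05, 148 by DESeq2 and 1943 by limma voom, and 1480 by edgeR without D+V replicate 1.

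Exact permutation tests of the scores of the other lists that kept their call with each library left out gave the following p. In S-V against Control it was 0.214 for glucocorticoid-responsive genes, 0.0357 for heat shock genes and 0.0536 for thalamus and habenula markers, and in D+V against Control 0.0714 for endothelial markers and 0.0357 for immediate early genes. In D-V against Control it was 0.0179 for red blood cell markers and 0.0536 for endoplasmic reticulum stress genes. In D-V against S-V it was 0.0397 for glucocorticoid-responsive genes, 0.0794 for ribosomal protein genes, 0.0476 for microglia markers, 0.0873 for dentate granule cell markers, 0.0476 for immediate early genes, 0.0238 for red blood cell markers, 0.0238 for thalamus and habenula markers and 0.0952 for AMPA, NMDA and kainate receptor genes. In D-V against D+V it was 0.0714 for endothelial markers, 0.0873 for astrocyte markers, 0.0556 for endoplasmic reticulum stress genes and 0.0397 for Y-linked and X-inactivation genes. In D+V against S-V it was 0.0556 for glucocorticoid-responsive genes, 0.127 for AMPA, NMDA and kainate receptor genes, 0.0317 for GABA signalling genes, 0.0714 for postsynaptic density genes, 0.135 for channel genes, 0.183 for oxidative phosphorylation genes, 0.23 for ribosomal protein genes and 0.0238 for Y-linked and X-inactivation genes. After adjustment over the 42 lists the smallest p in these 6 comparisons was 0.333. The smallest p that the splits allow is too large for a single list to pass this adjustment, so the adjusted values decide nothing. The mean of the rotated groups was not tested in this way. Replication-dependent histone genes, a list fixed for RNA quality and not called by camera in S-V against Control, had an exact permutation p of 0.0179 there. The mean score was −0.27 ± 0.15 in Control (SD, n = 3) and 0.13 ± 0.09 in S-V (SD, n = 5). It was 0.17 ± 0.37 in D+V and −0.13 ± 0.23 in D-V (SD, n = 5 each). This list was picked after its values were seen, and a difference in RNA or library quality was not tested.

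The activity and stress genes chosen in advance passed in none of the 7 comparisons by edgeR. Fos, a marker of recent firing, was at 16.3 ± 1.26 CPM in Control (SD, n = 3), 17.7 ± 3.45 in S-V, 12.5 ± 2.9 in D+V and 13.6 ± 5.04 in D-V (SD, n = 5). Arc, which regulates AMPA receptors, was at 166 ± 52.2, 175 ± 30.9, 127 ± 28.3 and 150 ± 42 CPM in the same order. In D+V against Control the smallest adjusted p among these genes was 0.123, for Npas4 (log2 −0.67, SE 0.22). Egr1 was at −0.29 (SE 0.14) in that comparison. Fkbp5, a co-chaperone induced by glucocorticoids, was at log2 0.19 (SE 0.11) in S-V, 0.13 (SE 0.11) in D+V and 0.14 (SE 0.11) in D-V against Control. The neurotrophin gene Bdnf was at 0.06, 0.03 and 0.06 (SE 0.17 each), and the histamine receptor genes Hrh1 and Hrh3 had adjusted p of 0.471 or more in the 7 comparisons.

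Libraries of the same group differed in choroid plexus, the tissue that secretes cerebrospinal fluid. Its marker Ttr, which encodes transthyretin, ranged from 49.3 to 990 CPM in Control, from 88.3 to 3790 in S-V, from 35.6 to 8350 in D+V and from 49.9 to 10000 in D-V. The first principal component held 25.1% of the variance, and 5 of the 6 libraries richest in these markers lay at −17.5 or lower on it, with no other library below −3.3. The second held 14.1%, and D+V libraries 2, 3 and 5 stood apart on it. With those 3 libraries left out the D+V count was 11, of which 3 were among the 139, with the 6 libraries rich in choroid plexus markers left out it was 0, and with the marker score as a covariate it was 344, including all 139.

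**Figure D4:**
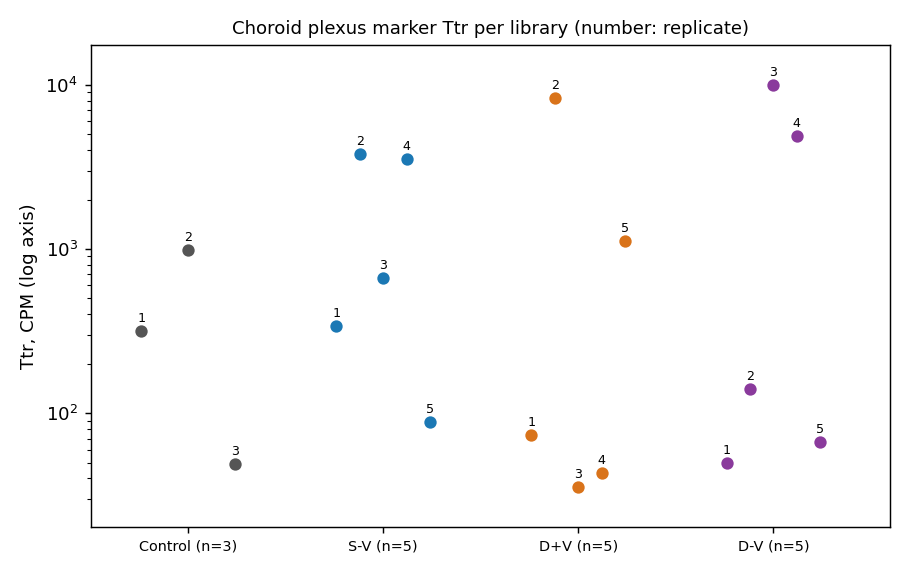
CPM of the choroid plexus marker Ttr in each library (vertical axis, log scale), by group; numbers are replicates. Libraries of the same group span the axis, as in D+V from 35.6 to 8350 CPM and in D-V from 49.9 to 10000 CPM, the highest in D-V replicate 3.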

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

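Of the tests weighed in this part, the library size, marker correlation, variance share, left-out S-V library and unadjusted p count tests, the removal of trends on GC content and length, the choroid plexus score as a covariate and the fits with choroid-rich libraries left out were chosen only after the result was seen. A library was singled out when its gap to the nearest other library of its group of 5 was large against the range of the group, which happens by chance in about 1 in 20 tests. It happened in 19 of 219 tests of 73 measures, where 11 were due by chance.

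The first pattern weighed was the set of 139 genes called in D+V against Control. A trend of each library on transcript GC content and length could account for the calls: with the trends removed 0 of the 139 stayed called, as the median absolute log2 fold change went from 0.386 to 0.184 and the median SE only from 0.0816 to 0.0702, with 100 (71.9%) at an unadjusted p under 0.05. On simulated data with a trend on GC content alone, equal in each D+V library, removal took false calls from 1520 of 1674 to 12 of 155. Of 100 genes with true 2-fold and 4-fold changes 92 were recovered, 95 before, and of 50 with 1.5-fold changes 32, 35 before. These changes were larger than the median of the 139, and the real trends included length and varied within groups. The simulation thus does not show that removal spares true changes as small as those of the 139. For library size, 3 of 3 controls lay within the range of D+V totals. Overlap of the totals cannot exclude a part of depth in the calls, as depth was not varied in any fit. The choroid plexus score as a covariate, with which 139 stayed called, argued against choroid plexus tissue as the whole source. Yet 0 genes were called with the 6 choroid-rich libraries left out, a fit on fewer samples. In D+V the median log2 fold change also fell across the bins of higher GC content, from −0.025 at 51.2% to −0.141 at 60.1%. These values argue against a true change confined to genes of low GC content. A true change that went with GC content over all bins could give the same trend, and these data cannot separate it from a technical cause.

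The second pattern was the spread of choroid plexus markers within groups. Deviations of the 25 markers from their group means had a median pairwise correlation of 0.954 over 300 pairs, in line with choroid plexus tissue in some dissected samples. The 4 groups held 4.71% of the variance of the score, with a permutation p of 0.867. As the pattern was picked for its spread within groups, this small share was to be anticipated, and an added effect of the rotation treatments stays open. The cause of the uneven tissue was not tested.

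The third pattern was the lower level of glucocorticoid-responsive genes in D-V than in S-V, a mean log2 of −0.28, which was −0.176 without S-V replicate 4, the library with the highest score, and left the test of a single S-V library undecided. The trends on GC content and length were excluded as the source, at −0.285 with the trends removed. The marker score as a covariate, at −0.266, argued against choroid plexus tissue as the whole source, though with the 6 libraries rich in its markers left out, S-V replicate 4 among them, the mean was −0.16. With an estimated correlation the adjusted p was 0.524 without S-V replicate 4, 0.162 with the covariate and 0.0579 with the trends removed. A hormonal difference between the groups could explain it, but hormone levels were not in the files.

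Chance was tested by counting other divisions of the same libraries into groups of the same sizes. All 56 divisions were used for each rotated group against Control. For the mean 60 of 816 possible divisions were used, and in each comparison between rotated groups 60 of 126. These were the real division and others drawn at random, so higher counts may exist. Chance could not be excluded for the 139 genes of D+V against Control: 4 of 56 divisions gave as many, and the highest other, which set Control replicates 1 and 2 with D+V replicate 1 against the rest, gave 2143. A count this far above the real one points to a structure of the samples other than the groups. The Spearman correlation of each library's log2 CPM, minus the mean of all libraries, with transcript length differed between the sides of that division. It was −0.291 and −0.313 in Control replicates 1 and 2 and −0.503 in D+V replicate 1. In the other libraries of these groups it ran from 0.262 to 0.502. Whether this trend gave the count was not tested. Nor could chance be excluded for the lists called: 7 in that comparison, reached by 49 of 56 divisions (highest other 23), 12 in S-V against Control, by 25 of 56 (22), 11 in D-V against Control, by 38 of 56 (21), 7 for the mean of the rotated groups, by 58 of 60 (20), 16 in D-V against S-V, by 11 of 60 (22), 7 in D-V against D+V, by 51 of 60 (24), and 15 in D+V against S-V, by 17 of 60 (18).

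In the other 6 comparisons the real count of genes was 0, which every division reaches, so these counts do not test chance. The divisions numbered 56 of 56 in S-V against Control (highest other 1), 56 of 56 in D-V against Control (27), 60 of 60 for the mean (2115, with D+V replicates 2, 3 and 5 set apart), 60 of 60 in D-V against S-V (0), 60 of 60 in D-V against D+V (369) and 60 of 60 in D+V against S-V (1929, with D+V replicate 1 on the S-V side in place of S-V replicate 2). The count of genes at an unadjusted p under 0.05, examined only afterwards, can test it. In S-V against Control it was 1973, reached by 1 of 56 divisions, the real one (highest other 1673), which is the smallest share that 56 divisions allow. With the trends on GC content and length removed it was 1240, and the other divisions were not recomputed in that way. The count therefore cannot tell an effect of rotation from these trends. Elsewhere it was reached by 4 of 56 in D+V and 10 of 56 in D-V against Control, 6 of 60 for the mean, 9 of 60 in D-V against S-V, 9 of 60 in D-V against D+V and 8 of 60 in D+V against S-V.

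Single libraries that stood apart are given with the gap over the range. S-V replicate 4 had 4 of the 19. Its score of cholinergic signalling genes was 0.16, with the other S-V libraries from −0.10 to −0.05 (0.789), its CA3 pyramidal cell score was −0.15 against 0.01 to 0.03 (0.867), Fos was at 23.6 CPM against 15.1 to 17.3 (0.751) and the histamine receptor gene Hrh3 at 56 CPM against 33.3 to 38.9 (0.752). D-V replicate 5 had 3: 15938 genes with a count against 16194 to 16281 (0.746), an immediate early gene score of 0.19 against −0.11 to −0.04 (0.752), and Arc at 224 CPM against 122 to 144 (0.785).

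D-V replicate 3 had Col4a2 at 46.4 CPM against 38 to 39.4 (0.823) and Fkbp5 at 59.3 against 66.4 to 68.8 (0.742). D-V replicate 4 had a GABA signalling score of −0.20 against −0.02 to 0.04 (0.747) and Cldn5 at 44.6 CPM against 35 to 37.7 (0.717), and D-V replicate 2 had a hypoxia score of −0.07 against −0.01 to 0.01 (0.726). D+V replicate 1 had Col4a2 at 29.1 CPM against 36 to 38.4 (0.736) and Bdnf at 30.7 against 35.7 to 37.5 (0.74). D+V replicate 2 had an inflammatory gene score of 0.27 against −0.14 to −0.05 (0.787), D+V replicate 3 a dentate granule cell score of −0.32 against 0.03 to 0.12 (0.776), and D+V replicate 4 Hspa13 at 54.8 CPM against 49.5 to 51 (0.722). S-V replicate 1 had a total of 24.3 M counts against 15.6 to 17.8 M (0.739), and Pdgfrb at 19.6 CPM against 22.6 to 23.4 (0.799).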

How the results depend on the processing

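The choroid plexus score as a covariate, removal of the GC and length trends, leaving out the 6 libraries rich in choroid plexus markers, and leaving out D+V libraries 2, 3 and 5 were chosen only after the result was seen. The other alternatives were fixed in advance. Of 166 recomputed gene counts 118 stayed within 1.5 times the reported one and 48 moved, and of 125 list counts 100 stayed and 25 moved. Single lists kept direction and side of the threshold in 947 of 1307 fits, were weaker in 351 and reversed in 9. Named genes did so in 808 of 1047 fits, with 147 weaker, 92 stronger and 0 reversed.

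Genes called, by setting, moved as follows, and the cause was not tested. With upper-quartile factors in edgeR they numbered 3 in S-V against Control, 88 in D+V against Control (69 of the 139), 2 for the mean of the rotated groups and 1 in D-V against D+V. By the DESeq2 Wald test they were 212 (S-V against Control), 759 (D+V against Control, 138 of the 139), 3 (D-V against Control), 259 (mean), 11 (D-V against S-V), 277 (D-V against D+V) and 148 (D+V against S-V). By limma voom with quality weights they were 318, 1882 (all 139), 381 (mean), 819 (D-V against D+V) and 1943 (D+V against S-V). With only the groups compared in the fit D+V against Control gave 0. That fit had fewer degrees of freedom and took its spread from D+V and Control libraries alone, and these were not tested apart. With an absolute log2 fold change of at least 1 D+V against Control gave 1.

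With the first surrogate variable, D+V against Control gave 392 genes, the mean 43 and D-V against D+V 3, and S-V against Control gave 7 lists. With the choroid plexus score as covariate these were 344, 33, 3 and 7 lists, and the choroid plexus list in D-V against Control turned to −0.037, as the construction of the covariate implies. With GC and length trends removed, genes numbered 5 in S-V, 0 in D+V and 3 in D-V against Control and 6 for the mean, and D+V against S-V gave 9 lists. Leaving out the 6 libraries rich in choroid plexus markers gave 1 gene in S-V and 0 in D+V against Control, and turned the choroid plexus list to −0.21 in S-V and −1.15 in D-V against Control. This turn is favoured by the choice of libraries by the same markers, all of them from rotated groups. Leaving out D+V libraries 2, 3 and 5 gave 11 genes in D+V against Control (3 of the 139) and 72 for the mean, and reversed astrocyte markers in D+V against Control (−0.002). In D+V against S-V it reversed heat shock genes (0.001), astrocyte markers (−0.04), endothelial and pericyte markers (0.005) and the list test of red blood cell markers, whose mean stayed positive at 0.049. Fewer libraries entered these fits, and the cause was not tested further.

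With a replicate block D+V against Control gave 4 genes and the mean 11 lists. The numbers did not pair libraries: over 24 pairs of the same number in different groups the median correlation was 0.007, as it was over 96 pairs of different numbers. With an estimated inter-gene correlation the lists called were 0 in S-V, 0 in D+V and 1 in D-V against Control, 0 for the mean, 0 in D-V against S-V, 0 in D-V against D+V and 0 in D+V against S-V, and with fry 0, 0, 1, 0, 0, 0 and 1 in the same order.

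With each library left out in turn, genes called ranged from 0 to 1 in S-V against Control, 0 to 1260 in D+V against Control, 0 to 0 in D-V against Control, 0 to 6 for the mean, 0 to 0 in D-V against S-V, 0 to 1230 in D-V against D+V and 0 to 1480 in D+V against S-V. The highest counts in the comparisons that include D+V came without D+V replicate 1. Lists called ranged from 8 to 18, 5 to 12 (11 without Control replicate 1, 12 without D+V replicate 1), 6 to 15 (7 without D-V replicate 3, 6 without D-V replicate 4), 5 to 16 (16 without Control replicate 1), 12 to 21, 7 to 13 (13 without D+V replicate 2 and without D-V replicate 5) and 11 to 19 in the same order. Dentate granule cell markers in D-V against Control reversed in the list test, with a mean of −0.01, without Control replicate 3, and was at −0.346 without Control replicate 1. On data simulated at the depths of the libraries 32.7% of 1.3-fold and 53.3% of 1.5-fold changes were recovered in D+V against Control, so absence of a call is not absence of change. Depth itself was not varied.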

Other observations

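Red blood cell transcripts, which come from blood left in tissue, were lowest in Control. Of the tests in this part, the removal of trends on GC content and length and the fits with 6 libraries or D+V libraries 2, 3 and 5 left out were chosen only after the result was seen. Hbb-bs, an adult beta-globin gene, was at 223 ± 32.9 CPM in Control (SD, n = 3), 341 ± 73.2 in S-V, 637 ± 444 in D+V and 511 ± 128 in D-V (SD, n = 5 each). In D+V against Control Alas2, the heme synthesis enzyme of red cells, was at log2 1.57, Hbb-bt at 1.55 and Hba-a2 at 1.46, and adjusted over the list alone 6 of 12 members rose, with adjusted p = 0.688 with an estimated correlation for the list. With the 6 libraries rich in choroid plexus markers left out, or D+V libraries 2, 3 and 5, the list mean was 0.51 and 0.29 and no longer called. For the mean of the rotated groups the list was at 0.74 (adjusted p = 0.786 with an estimated correlation), at 0.63 and no longer called without Control replicate 3, at 0.47 with those 6 libraries left out and at 0.43 without D+V libraries 2, 3 and 5.

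Sex-linked genes were called as a list between rotated groups only while the trends on GC content and length were left in. The Y-linked gene Ddx3y, an RNA helicase, was at log2 0.53 in D+V against S-V and −0.53 in D-V against D+V, and Uty, a histone demethylase, at −0.43 in D-V against D+V. All 4 members of the list of Y-linked and X-inactivation genes were positive in D+V against S-V (mean 0.33, adjusted p = 0.34 with an estimated correlation) and all 4 negative in D-V against D+V (mean −0.30, adjusted p = 0.593 with an estimated correlation). Adjusted over the list alone 3 rose in D+V against S-V and 2 fell in D-V against D+V. With the trends removed the means were 0.17 (adjusted p 0.0849 at the preset correlation) and −0.08 (adjusted p 0.572), without D+V libraries 2, 3 and 5 they were 0.09 and −0.07, and with the 6 libraries rich in choroid plexus markers left out the latter was −0.19, none of them called.

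Some genes passed with the trends on GC content and length removed but not in the edgeR fit without this removal. They were chosen after their values were seen, and the removal itself was added after seeing the data. With the trends removed Zfp994 fell by a log2 of −1.01 in S-V against Control (SE 0.17, adjusted p 0.035). In D-V against Control it fell by −1.07 (adjusted p 0.0279). Its CPM was 5.47 ± 0.432 in Control (SD, n = 3) and 5.13 ± 1.28 in D+V (SD, n = 5). It was 2.92 ± 0.2 in S-V and 2.68 ± 0.548 in D-V (SD, n = 5 each), the groups with vision blocked. A dependence on vision was not shown. With the trends removed 0 genes were called in D-V against D+V and 0 in D+V against S-V. The others were Ttc14 (−0.60 in S-V, adjusted p 0.0045, and −0.50 in D-V), Olfr1385 (−0.52 in S-V and −0.58 in D-V), Zcchc7 (−0.63, adjusted p 0.0183) and Bloc1s4, a subunit of the lysosome biogenesis complex BLOC-1 (0.52, adjusted p 0.0183), the latter pair in S-V alone. For the mean of the rotated groups 6 passed: these 5 and Pcp4, a calmodulin-binding protein (−0.39). Zfp994 sits in a family of similar genes, so its counts are uncertain.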
